A study of Oryza sativa with 12 samples.

How the data were processed

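The series holds 12 arrays of root RNA from the rice varieties Azucena and Bala, with and without arsenate, in 3 independent experiments that each gave 1 array to each of the 4 groups. Plants grew for 7 days (1 week) in hydroponic solution with 0 or 1 ppm (13.3 uM) arsenate under 12 hours of light, and each sample was 100 mg of root from 4 plants, of which 5 ug total RNA was labelled. The deposited values are intensity, given by the authors as MAS5 probe set signals (per the submitters' processing notes, which give no version). On all 12 arrays the mean of the deposited signals after trimming 2% at each end was 100.0, and no value was negative, so they were taken as linear signals scaled to a common target.

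Analyses used R 4.3.3 and limma 3.58.1. Affymetrix control probe sets (123) were left out of the tests, which left 57258. Values were taken as log2(signal + 2.1), where 2.1 was the 25th percentile of all signals, and probe sets with a mean signal above the pooled median of 9.4 were tested (28461). The deposited scaling was kept. Limma was fitted to all 12 arrays with 4 group means and the experiment as a block (6 residual and 2.85 prior degrees of freedom). Contrasts were arsenate in Azucena, arsenate in Bala, their average, their difference (Bala minus Azucena), and Bala minus Azucena without and with arsenate. The p values were adjusted by Benjamini and Hochberg's method within each contrast, with a threshold of 0.05. Array number limits the precision. As a check on the experiment numbers, deviations from the group mean were correlated between arrays of different groups: the median r was 0.131 over 18 pairs of the same number (11 above 0.1) and -0.0359 over 36 other pairs (7 above 0.1). Deviations sum to 0 within a group, so that the 2 values are not independent. Pairs within experiment 1 ran from -0.0975 to 0.195, and pairs of experiment 1 with 2 from -0.182 to 0.323. The check therefore does not part experiments 1 and 2.

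Probe sets were named through an annotation table that gave 1 gene for 22436, several for 95 and none for 34727, in all 17905 genes of which 2457 had a name other than a locus. The table gave names and chromosomes but no descriptions. Where a gene had several probe sets, that with the highest mean was used, which left 15638 genes. Gene lists, the contrasts, the threshold and the naming rule were chosen before the data were examined. The lists were written as words of gene descriptions and had to be restated as patterns of gene symbols once the annotation was seen to hold no descriptions, before any test was run. Membership therefore rests on symbols, and what each member does was not checked. Apart from the chromosome 6 list, only the 2457 genes with a name could match. Counts and tests of a list cover its named members and not the whole gene family. Of 31 single loci listed 22 matched 1 measured gene by name, and OsPT2 (OsPht1;2) matched 2. The arsenic and thiol loci OsPCS1, OsPCS2, OsABCC1, OsHAC1;1 and OsHAC1;2 matched none, nor did OsPHO2, OsIPS1 and OsDMAS1. Lists share members, for example Lsi2 and both NIP channels with the potassium and metal transporters. Lists with at least 5 members were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and 38 lists were tested, 3 were too small and 3 had no matched gene.

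The naming rule took, for each of 4 contrasts, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold that changed in the same direction in all 3 experiments, then up to 4 members of each list with the smallest adjusted p in either variety, and the single loci. It gave 194 genes. Members of small counts outside that rule were named after their values were seen. Of the named genes 40 were on probe sets that can match several transcripts, 32 had another tested probe set, 21 of these with the same call and 2 with the opposite call.

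Alternatives were no replicate block, pseudocounts at the 5th (0.4) and 50th percentile, no filter and a filter at the 70th percentile (49.1), quantile normalization, centring each array on its median, limma's trend and robust options, fits of only the groups compared, and leaving out each array and each experiment. A fit without Azucena control 3 and Bala arsenate 3 was added after the data were seen. When the fit was tested on simulated data, 19 of 100 probe sets with an added change of 1 log2 unit and 61 of 100 with 2 were recovered in the Azucena contrast, with 6 false calls, and 0 and 32 of 100 in the difference (0 false calls). Without an added change there were 0 calls. A simulated list of 30 genes had a camera p of 6.69e-36 when shifted and 0.0657 when not. The simulated probe sets varied independently of each other, so that the simulation does not bear on correlation between genes. Probe-level files of the arrays were not used here.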

Results

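RNA from the roots of 2 rice varieties, Azucena and Bala, grown with or without arsenate, was measured on 12 arrays of the Affymetrix Rice Genome design. Bala is known as the more arsenate-tolerant variety and Azucena as the more sensitive, and the series cites an arsenate tolerance gene on chromosome 6. The 4 groups were Azucena control, Azucena arsenate, Bala control and Bala arsenate, with 3 arrays each. Arsenate was given at 1 ppm (13.3 uM) in hydroponic solution for 7 days, and each replicate number was an independent experiment that held all 4 groups. The median signal of an array lay between 7.3 and 10.3, the highest signal between 6446 and 10160, and 46.0 to 51.9% of the probe sets of an array read above the filter value of 9.4. The number of arrays limits the precision. After that filter 28461 of 57258 probe sets were tested, which held 15638 genes counted with 1 probe set each. Across probe sets, arrays of the same group correlated with r between 0.916 and 0.974. On the 1000 most variable probe sets, component 1 (60.3% of the variance) parted the varieties and component 2 (29.7%) parted arsenate from control. Named genes are given as log2 change ± SE with 3 arrays per group, or as mean signal ± SD (n = 3), and every named change that passed the test had the same sign in all 3 experiments. Where a group read below the filter value, the size of a log2 change depends on the constant of 2.1 added to the signal. Gene lists, apart from that of chromosome 6, hold only genes with a matching symbol, so their counts and tests do not cover whole gene families.

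In Azucena roots, arsenate raised some genes of small heat shock proteins, dehydrins, iron acquisition and diterpenoid phytoalexins and the sugar transporter OsSWEET12, and lowered some transporters of zinc, manganese, copper, phosphate and silicon. OsHsp18.1, a small heat shock chaperone on chromosome 3, went from a signal of 17.2 ± 5.0 to 4006 ± 1096 (log2 change 7.69 ± 0.59). OsSWEET12, of the SWEET family of sugar transporters, went from 3.03 ± 3.44 to 683 ± 284 (log2 change 7.17 ± 0.37). The control signal of OsSWEET12 lay below the filter value, and its log2 change was 8.03 with a pseudocount at the 5th percentile and 5.75 at the 50th. OsZIP1, of the ZIP family of zinc and iron transporters, went from 1737 ± 131 to 20.7 ± 9.15 (log2 change -6.33 ± 0.33). The comparison asks which transcripts respond to arsenate in the sensitive variety. By limma with the experiment as a block, 5989 probe sets passed the test (3045 higher, 2944 lower), or 3555 genes (1945 higher, 1610 lower). A change of at least 4-fold was reached by 716 of the higher and 813 of the lower probe sets. Among genes with no name other than a locus, LOC9267997 (8.46 ± 0.58), LOC4350823 (7.75 ± 0.86) and LOC4333209 (7.01 ± 0.28) rose, and LOC4329797 (-7.80 ± 0.42), LOC4347027 (-7.04 ± 0.55) and LOC4342187 (-6.70 ± 0.23) fell. Control signals of these 3 that rose, and the arsenate signal of LOC4329797, lay below the filter value. The probe set of LOC9267997 can match several transcripts. The count was 2920, 2683 and 3776 without Azucena control 1, 2 and 3, and 3406 and 2970 without Azucena arsenate 1 and 2. Centring each array on its median moved the median change of all probe sets from 0.10 to 0.19, and the higher share of the calls from 50.8 to 57.8%.

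Of 32 heat shock proteins and chaperones measured, 16 rose and 2 (OsDjA6 and OsHsp18.8) fell in Azucena. Besides OsHsp18.1, OsHsp16.9B rose by 4.72 ± 0.53, OsHsp17.4 by 4.69 ± 0.44 and OsHsp26.2 by 4.29 ± 0.35. The number past the test adjusted over the list alone was 18, and limma's camera gave an adjusted p = 0.00151 for the list, with an adjusted p = 0.741 when the correlation between genes was estimated. Among 26 abscisic acid and LEA genes, 7 rose and 3 (DRR1, OsSAPK3 and OsSAPK4) fell. RAB21 (6.46 ± 0.58), RAB16B (5.00 ± 0.59) and LEA19 (4.05 ± 0.40), hydrophilic proteins known from water deficit and seed drying, were among the 7. Control signals of OsHsp16.9B, RAB21 and RAB16B lay below the filter value. Counted as adjusted over the list alone, 11 passed, and camera's adjusted p was 0.729, or 0.851 with an estimated correlation. In the thiol genes, gcs, which encodes the first enzyme of glutathione synthesis, rose by 1.56 ± 0.17 (limma adjusted p = 8.0e-04), and SAT4, a serine acetyltransferase of cysteine synthesis, by 4.44 ± 0.40 (limma adjusted p = 3.5e-04). Of 6 glutathione S-transferases 2 rose, GSTZ5 by 3.38 ± 0.46 and GSTU6 by 2.70 ± 0.55. GSTU6 had an adjusted p of 0.0517 without Azucena control 1 and 0.0551 without Azucena control 2. For these glutathione S-transferases camera's adjusted p was 0.531, and for the 6 sulfate genes, of which SAT4 alone passed, 0.251, or 0.871 and 0.741 with an estimated correlation. Adjusted over the list alone the counts were 2 and 1.

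Single metal transport genes moved in both directions in Azucena. Of 69 potassium and metal transporters 7 rose and 22 fell. OsNramp5, the root uptake transporter of manganese and cadmium, fell by 3.93 ± 0.21, OsCOPT1, of a family of copper transporters, by 4.61 ± 0.36, and OsVIT1.2, of the vacuolar iron transporter family, by 4.37 ± 0.37. Of the list, 33 passed when adjusted over the list alone (9 higher, 24 lower), and camera's adjusted p was 0.00151, or 0.741 with an estimated correlation. Of 12 iron acquisition genes 6 were higher and none was lower. OsNramp1, a metal transporter, rose by 5.23 ± 0.76, and OsNAS2, a nicotianamine synthase, by 3.82 ± 0.49. The bHLH factor of iron regulation IRO3, to which the annotation also gives the name OsIRO2, rose by 3.35 ± 0.44. Adjusted over the list alone 6 passed, camera's adjusted p was 0.0611, and with an estimated correlation the adjusted p was 0.741.

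Of 21 phosphate genes 7 were lower in Azucena and none was higher. OsPht1;2, a root phosphate transporter, went from 1320 ± 246 to 54.8 ± 21.3 (log2 change -4.59 ± 0.43). OsMGD3, a galactolipid synthase induced by phosphate starvation, fell by 1.73 ± 0.23, and OsSPX1 and OsSPX2, of the SPX family of phosphate signalling proteins, by 1.59 ± 0.32 and 2.19 ± 0.39. Without Azucena control 3 and Bala arsenate 3 together OsSPX1 did not pass (adjusted p 0.0546). Other phosphate transporters did not pass: the log2 change was -0.38 ± 0.28 for OsPht1;1, -2.07 ± 0.74 for OsPht1;4 and 0.27 ± 0.55 for OsPht1;8. The number past the test adjusted over the list alone was 8, camera's adjusted p was 0.0196 (0.0990 without Azucena arsenate 1), and with an estimated correlation the adjusted p was 0.741. The silicon channels and exporter known to carry arsenite made up the 3 lower genes among 6 arsenic handling genes. Lsi2, the exporter, went from 4148 ± 175 to 542 ± 91.0 (log2 change -2.94 ± 0.43), OsNIP2;2 (Lsi6) fell by 2.24 ± 0.32, and OsNIP2;1 (Lsi1) fell by 1.43 ± 0.37. The OsNIP2;1 call rested on single arrays, with an adjusted p of 0.0959 and 0.119 without Azucena control 1 and 2, and 0.113 and 0.0849 without Azucena arsenate 1 and 2, and 0.0738 without the filter. The annotated arsenate reductases did not pass, with -0.16 ± 0.18 for OsACR2.1 and 0.16 ± 0.15 for OsACR2.2. Counted as adjusted over the list alone, 3 passed, and camera's adjusted p was 0.0527, or 0.741 with an estimated correlation.

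Some water channel and nitrogen genes were lower in Azucena as well. Of 21 aquaporins 1 (OsNIP1;1) rose and 7 fell, among them OsPIP2;6 of the plasma membrane (-1.74 ± 0.20) and OsTIP4;1 of the vacuole (-1.32 ± 0.20). The silicon channels OsNIP2;1 and OsNIP2;2 are in this list too. Of the list, 8 passed when adjusted over the list alone, and camera's adjusted p was 0.00278, or 0.741 with an estimated correlation. Of 18 nitrogen uptake and assimilation genes 7 fell and none rose, including the ammonium transporters OsAMT3;3 (-2.54 ± 0.39) and OsAMT2;2 (-1.08 ± 0.22) and the cytosolic glutamine synthetase OsGLN1;2 (-1.51 ± 0.29). OsAMT2;2 did not pass without Azucena control 3 and Bala arsenate 3 together (adjusted p 0.0522). Adjusted over the list alone 11 passed, and camera's adjusted p was 0.00992, or 0.741 with an estimated correlation. Of 19 genes of photosynthesis, which mark green shoot tissue, 3 fell. The mean over the 19 was 5.64 ± 0.89 (SD, n = 3) on the log2 scale in Azucena controls and 4.23 ± 0.36 with arsenate. The highest control was replicate 3 at 6.64. ISP (-2.80 ± 0.54), OsGLK1 (-2.77 ± 0.57) and LP02 (-2.44 ± 0.53) passed, LP02 not without Azucena control 3 (adjusted p 0.0563), and OsGLK1 read below the filter value with arsenate. The number past the test adjusted over the list alone was 3, camera's adjusted p was 0.00894 (0.129 without Azucena arsenate 3), and with an estimated correlation the adjusted p was 0.741.

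Several defence genes rose in Azucena. Of 10 diterpenoid phytoalexin genes 7 were higher and 1 was lower. OsMAS, which makes momilactone A, rose by 5.84 ± 0.83, OsCPS4, an early enzyme of the same pathway, by 5.08 ± 0.81, and CYP99A2, a P450 of the same cluster on chromosome 4, by 3.35 ± 0.57. CYP76M7, a P450 of phytocassane synthesis, fell by 3.39 ± 0.47. Control signals of OsMAS, OsCPS4 and CYP99A2, and the arsenate signal of CYP76M7, lay below the filter value. Counted as adjusted over the list alone, 8 passed, and camera's adjusted p was 0.0527, or 0.741 with an estimated correlation. Of 23 pathogenesis-related proteins and chitinases 9 rose and 5 (OsGER1, OsGER2, OsGER4, Cht10 and OsAsp1) fell, with the chitinases OsChia2a at 3.06 ± 0.31, Cht11 at 3.38 ± 0.36 and LOC4351188, with a control signal below the filter value, at 4.80 ± 0.56. Of the list, 14 passed when adjusted over the list alone, and camera's adjusted p was 0.460, or 0.851 with an estimated correlation. Of 6 WRKY factors OsWRKY24 (3.67 ± 0.54) and OsWRKY71 (2.08 ± 0.48) rose, and OsWRKY71 had an adjusted p of 0.0817, 0.0623 and 0.0518 without Azucena control 2, Azucena arsenate 2 and Azucena arsenate 3. Adjusted over the list alone 3 passed, and camera's adjusted p was 0.156, or 0.741 with an estimated correlation. Of the 194 genes named by the rule given for the processing 147 passed in Azucena, and 43 of these were lost without a single array, 84 without a whole experiment and 37 in another setting. As a reading of RNA quality, the 3' to 5' signal ratio of the GAPDH control probe sets was 7.58 to 8.60 in Azucena controls and 8.86 to 23.8 with arsenate, while the ranges overlapped for actin (2.24 to 6.87 and 5.15 to 8.45) and cyclophilin (2.08 to 2.54 and 2.46 to 3.23).

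In Bala roots, arsenate raised some genes of the same kinds, among them small heat shock proteins, dehydrins and iron acquisition genes, and lowered some zinc, manganese and phosphate transporters. RAB21, a dehydrin on chromosome 11, went from 3.50 ± 4.77 to 1346 ± 469 (log2 change 8.18 ± 0.58, or 9.15 with a pseudocount at the 5th percentile and 6.72 at the 50th). OsIRT2, an iron transporter on chromosome 3, went from 8.60 ± 6.42 to 402 ± 94.1 (log2 change 5.49 ± 0.49). OsSWEET1b, a sugar transporter of the SWEET family on chromosome 5, went from 0.667 ± 0.289 to 111 ± 6.68 (log2 change 5.35 ± 0.18). The comparison asks which transcripts respond in the tolerant variety. By limma 3379 probe sets passed (1762 higher, 1617 lower), or 1985 genes (1092 higher, 893 lower), and 587 higher and 405 lower probe sets changed at least 4-fold. LOC4351985 (8.64 ± 0.33), LOC9267997 (7.70 ± 0.58) and LOC4326149 (7.54 ± 0.55) rose most among genes without another name, and LOC4329797 (-7.46 ± 0.42) and LOC4347027 (-7.33 ± 0.55) fell most. The Bala control signals of RAB21, OsIRT2, OsSWEET1b, LOC4351985 and LOC9267997 lay below the filter value, those of OsSWEET1b and LOC4351985 also below 2.1. The count was 1827 and 2061 without Bala control 1 and 2, and 1427 and 1693 without Bala arsenate 1 and 2. Centring each array on its median moved the median change of all probe sets from 0.06 to -0.10 and the higher share of the calls from 52.2 to 36.2%.

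Of the 32 heat shock proteins and chaperones 13 rose and 2 (OsDjA6 and OsHsp18.8) fell in Bala. OsHsp18.1 rose by 7.44 ± 0.59, OsHsp16.9B by 7.09 ± 0.53, OsHsp26.7 by 7.07 ± 0.95, OsHsp17.4 by 5.86 ± 0.44 and OsHsp18.0 by 5.59 ± 0.38. Control signals of OsHsp16.9B and OsHsp26.7 lay below the filter value. The number past the test adjusted over the list alone was 19, and camera's adjusted p was 9.9e-07, or 0.684 with an estimated correlation. Of 12 iron acquisition genes 8 rose and none fell. With OsIRT2 these were led by OsNramp1 (6.07 ± 0.76), OsIRT1 (4.59 ± 0.69) and IRO3, also annotated as OsIRO2 (4.28 ± 0.44). Counted as adjusted over the list alone, 9 passed, and camera's adjusted p was 8.9e-04, or 0.737 with an estimated correlation. Single sulfur and thiol genes rose. SAT4 rose by 2.97 ± 0.40, the cysteine synthase at LOC4352839 by 2.01 ± 0.35 and SAT5 by 1.02 ± 0.20, the 3 that passed among 6 sulfate genes. SAT5 had an adjusted p of 0.0579 without Bala control 2 and 0.0570 without Bala arsenate 2. The list had a camera adjusted p of 0.0437, which was 0.0550 and 0.0555 without Azucena control 1 and 3, 0.0559, 0.0504 and 0.0578 without Azucena arsenate 1, 2 and 3, 0.104 without Bala control 2 and 0.0885 without Bala arsenate 2. With an estimated correlation the adjusted p was 0.737, and adjusted over the list alone 4 passed. gcs rose by 1.24 ± 0.17, and of the glutathione S-transferases GSTZ5 rose by 4.66 ± 0.46, GST1 by 2.77 ± 0.36 and GSTU6 by 2.87 ± 0.55 (adjusted p 0.0523 without Bala arsenate 2), with a camera adjusted p of 0.0775, or 0.827 with an estimated correlation, and 3 past the test adjusted over the list alone.

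Some phosphate, silicon and water transport genes fell in Bala. Of 21 phosphate genes 1 rose and 4 (OsPht1;2, OsMGD3, OsSPX1 and LPR4) fell. OsPht1;2 fell by 3.72 ± 0.43, and the ferroxidase LPR1 of root responses to low phosphate rose by 3.94 ± 0.54. OsMGD3 had -1.19 ± 0.23 (adjusted p 0.0539 without Bala control 1, 0.0576 without Bala arsenate 1). OsSPX1 had -1.37 ± 0.32, with an adjusted p of 0.107 and 0.0964 without Bala control 1 and 2, and 0.0695, 0.102 and 0.0729 without Bala arsenate 1, 2 and 3. Of the list, 6 passed when adjusted over the list alone, and camera's adjusted p was 0.0131 (0.0906 without Bala control 1), or 0.779 with an estimated correlation. Lsi2 was the 1 of 6 arsenic handling genes that fell, by 3.08 ± 0.43. Adjusted over the list alone 2 passed, and camera's adjusted p was 0.0358 (0.116 without Bala control 1), or 0.737 with an estimated correlation. Of 21 aquaporins 4 fell, OsTIP4;1 by 1.33 ± 0.20, OsTIP1 by 1.49 ± 0.28, OsPIP2;2 and OsPIP2;4. The OsTIP1 call rested on the block: without it the change was -1.49 with an adjusted p of 0.316, and OsTIP1 was lost without experiment 1 (0.114) or 2 (0.0720) as well. The number past the test adjusted over the list alone was 6, and camera's adjusted p was 0.00513, or 0.737 with an estimated correlation. Among the 69 potassium and metal transporters 9 rose and 17 fell, with OsZIP1 at -4.57 ± 0.33, OsVIT1.2 at -3.12 ± 0.37 and OsNramp5 at -2.26 ± 0.21. The median of this list was 0.01 and its mean -0.14, 38 passed adjusted over the list alone, and camera's adjusted p was 0.169, or 0.827 with an estimated correlation. Of 18 nitrogen genes 1 (Fd-GOGAT) rose and 3 (OsGLN1;2, OsAMT2;2 and the ammonium transporter OsAMT1;2, at -3.10 ± 0.50) fell, where OsGLN1;2 passed without Azucena arsenate 1 or 3 but not without any other single array (adjusted p 0.0711 to 0.166). The list had 6 past the test adjusted over the list alone and a camera adjusted p of 0.169, or 0.827 with an estimated correlation.

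Some jasmonate and phytoalexin genes fell in Bala with arsenate. Of 37 jasmonate genes 4 (OsOPR1, OsOPR4, OsOPR5 and OsOPR6) rose and 6 fell. OsOPR1, an oxophytodienoate reductase, rose by 4.43 ± 0.64, while the lipoxygenase LOX3 fell by 3.27 ± 0.40 and the factor OsJAMyb by 2.61 ± 0.38. Counted as adjusted over the list alone, 13 passed, and camera's adjusted p was 0.0107 (0.0747 without Bala control 1, 0.0514 without Bala control 2), or 0.827 with an estimated correlation. Of 10 phytoalexin genes 2 fell, CYP99A2 by 2.63 ± 0.57 and OsDTS2. The CYP99A2 call had an adjusted p of 0.0759 without Bala control 1 and without Bala control 2, 0.0917 without Bala arsenate 1 and 0.0724 without Bala arsenate 3. Of the list, 4 passed when adjusted over the list alone, and camera's adjusted p was 0.0131 (0.0747 without Bala control 1, 0.0798 without Bala control 2), or 0.827 with an estimated correlation. The shoot markers had a mean of 6.79 ± 0.68 (SD, n = 3) in Bala controls and 5.48 ± 1.53 with arsenate, where replicate 3 stood at 7.20. Of these 19 genes ISP (-2.58 ± 0.54) and OsGLK1 (-2.89 ± 0.57) passed, ISP with an adjusted p of 0.0664 without Bala control 2, 0.0777 without Bala arsenate 1 and 0.0653 without Bala arsenate 2, and OsGLK1 with 0.0575 without Bala control 1, 0.0683 without Bala arsenate 1 and 0.0620 without Bala arsenate 2. OsGLK1 read below the filter value with arsenate. Adjusted over the list alone 2 passed, and camera's adjusted p was 0.0115 (0.0958 without Bala control 2, 0.101 without Bala arsenate 2), or 0.827 with an estimated correlation. Of the 194 named genes 111 passed in Bala, and 32 of these were lost without a single array, 68 without a whole experiment and 29 in another setting. The GAPDH 3' to 5' ratio was 1.43 to 2.17 in Bala controls and 3.53 to 3.79 with arsenate, and that of actin 2.54 to 3.66 and 6.82 to 8.59, while the ranges overlapped for cyclophilin (1.88 to 2.44 and 2.08 to 2.90).

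**Figure D1:**
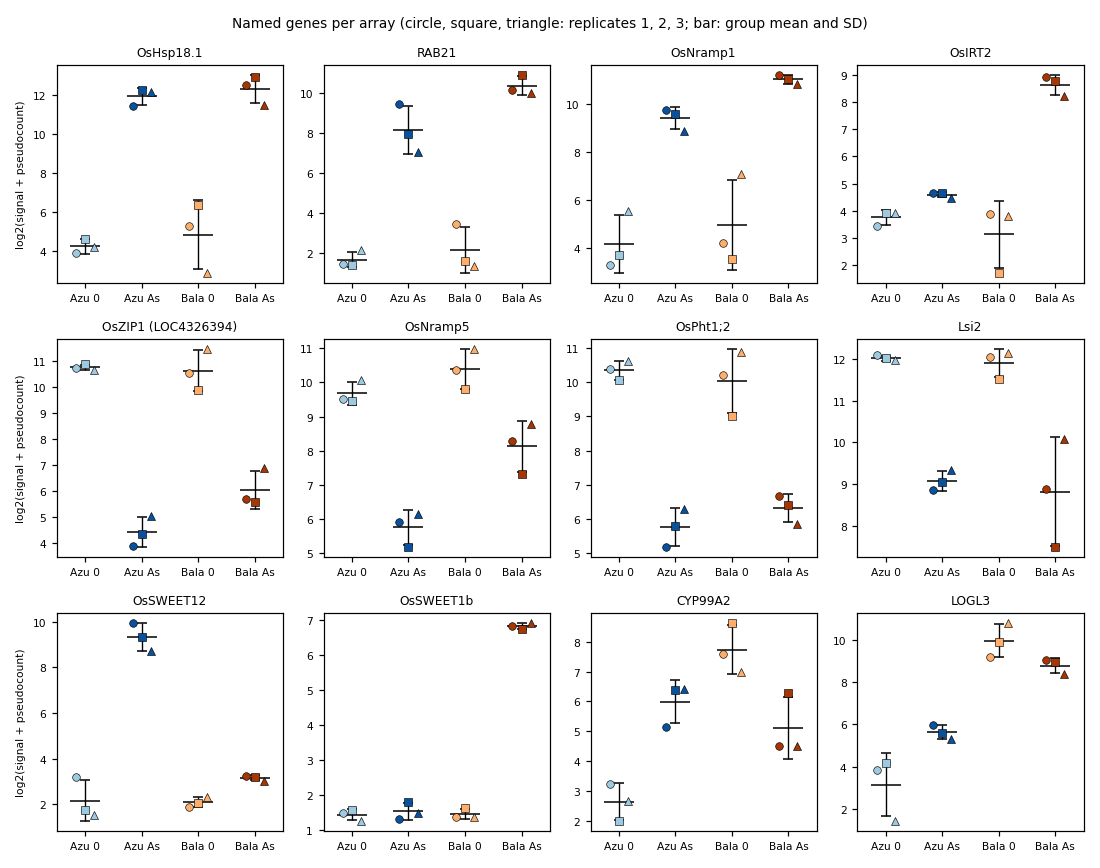
log2(signal + 2.1) of 12 named genes on each of the 12 arrays; Azu and Bala mark the variety, 0 the control and As arsenate, and the bar gives the group mean and SD (n = 3). OsSWEET12 was high only in the arsenate arrays of Azucena (683 ± 284) and OsSWEET1b only in those of Bala.

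Part of the response was shared between the varieties. Averaged over both, 9033 probe sets passed limma's test (4896 higher, 4137 lower), 618 of them at least 4-fold higher and 566 at least 4-fold lower. Centring each array on its median gave 3908 higher and 4093 lower, so that the higher share went from 54.2 to 48.8%. Among the named genes, OsHsp18.1 had an average change of 7.56 ± 0.42, RAB21 of 7.32 ± 0.41, SAT4 of 3.70 ± 0.28, OsPht1;2 of -4.15 ± 0.30 and OsZIP1 of -5.45 ± 0.24. Of the probe sets higher in Azucena, 1130 were also higher in Bala, where lists drawn independently would share 188.5, and of the lower ones 1103 were also lower in Bala, against 167.3. Opposite calls were 9 and 13. Both contrasts came from 1 fit with a shared spread per probe set. Calls could therefore overlap more than independent lists without a common response. Across probe sets, which are not independent replicates, the changes in both varieties correlated with Pearson's r of 0.706 and Spearman's rho of 0.624, from arrays that were not shared. In both varieties the GAPDH 3' to 5' ratio was higher with arsenate, and the shoot markers were lower on average. Their part in the shared response was not tested.

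The difference between the varieties in their arsenate response asks which genes respond in 1 variety more than in the other. OsSWEET12 rose in Azucena (7.17 ± 0.37) and had 1.07 ± 0.37 in Bala, a difference (Bala minus Azucena) of -6.10 ± 0.52 (limma adjusted p = 0.00830). OsSWEET1b had 0.09 ± 0.18 in Azucena and rose by 5.35 ± 0.18 in Bala, a difference of 5.26 ± 0.25 (limma adjusted p = 1.9e-04). Both genes read below the filter value where they did not rise, so that the sizes depend on the pseudocount: the difference was -6.50 for OsSWEET12 and 6.51 for OsSWEET1b at the 5th percentile, and -5.26 and 3.55 at the 50th. CYP99A2 rose in Azucena and fell in Bala, with a difference of -5.98 ± 0.81 (limma adjusted p = 0.0485). At the 5th percentile CYP99A2 did not pass (adjusted p 0.0821), nor did LOC4334549 (0.0719), LOC4339856 (0.0804) and LOC4342259. The median difference of all probe sets moved from -0.03 to -0.28 when arrays were centred on their median, and the higher share of the calls from 46.2 to 28.2%. Limma called 26 probe sets, 12 with a positive and 14 with a negative difference, which held 11 genes, and 14 of the 26 had no gene in the annotation.

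LOC4343962, LOC4334549, LOC4339856, LOC4342259, LOC4326000 and LOC4326969 also differed with a higher response in Azucena, by -4.30, -4.97, -3.80, -2.74, -3.37 and -3.56. LOC4344909 (-3.91 ± 0.28 in Azucena, 0.54 ± 0.28 in Bala) and LOC9267438 (-0.14 ± 0.21 and 2.71 ± 0.21) had positive differences of 4.45 and 2.85. The probe set of LOC4344909 can match several transcripts, and another probe set of this gene differed by 3.27. LOC4339856 lies on chromosome 6, as the 1 gene of 1229 measured there that passed. With 11 of all 15638 genes past the test, that is near the share over all genes. The number of calls rested on single arrays. It was 18, 5 and 7 without Azucena control 1, 2 and 3, 32, 7 and 74 without Azucena arsenate 1, 2 and 3, 5, 9 and 97 without Bala control 1, 2 and 3, and 8, 18 and 11 without Bala arsenate 1, 2 and 3. Without experiment 1, 2 or 3 limma called 0, with 2114, 1461 and 4773 probe sets at an unadjusted p under 0.05, and without the replicate block it called 58. OsSWEET1b, OsSWEET12 and LOC4343962 passed without any single array, and LOC4344909 without any but Bala control 1 (adjusted p 0.0533). The other 7 genes were lost without Azucena control 2 (adjusted p 0.0582 to 0.150), Azucena arsenate 2 (0.0995 to 0.159), Bala control 1 (0.0596 to 0.0995) or Bala control 2 (0.0745 to 0.138), and CYP99A2 was lost without any array but Azucena control 1 and Bala control 3. All 11 were lost when any 1 of the experiments was left out. LOC9267438 was also lost without the replicate block (adjusted p 0.105) and with trend and robust options (0.0508), LOC4339856 with these options (0.0508), and LOC4342259 with them (0.0860) and with quantile normalization (0.0512). Without the filter 7 of the 11 were lost (0.0833 to 0.115), and without Azucena control 3 and Bala arsenate 3 together all but OsSWEET1b (0.0892 to 0.164). All 11 but LOC4326000 read below the filter value in at least 1 group.

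**Figure D2:**
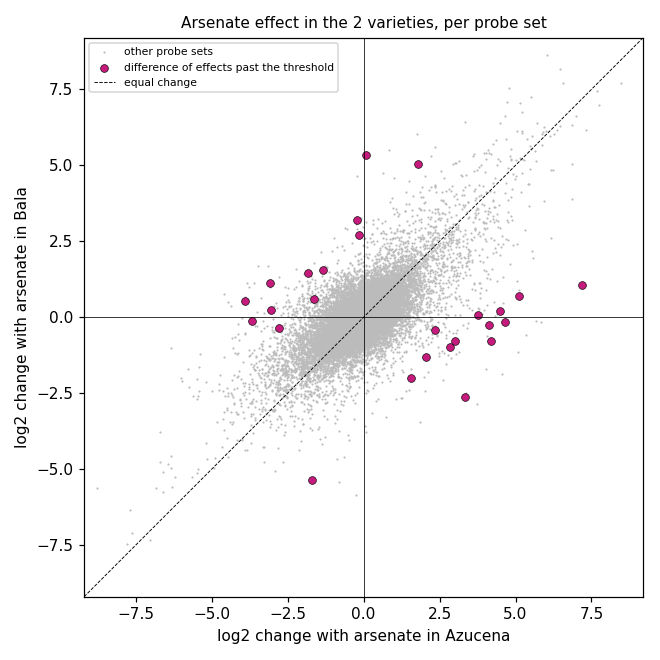
Log2 change with arsenate of each of the 28461 probe sets in Azucena (x axis) and in Bala (y axis), with the line of equal change. The 26 probe sets whose difference passed the test are marked; Pearson's r over all probe sets was 0.706.

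Some gene lists differed between the varieties in their response with the preset correlation only. The 10 diterpenoid phytoalexin genes had a mean difference of -3.53 (median -3.40), CYP99A2 passed over all genes and 9 genes passed adjusted over the list alone (1 higher, 8 lower). OsMAS had a difference of -5.99 ± 1.18 and OsCPS4 of -6.24 ± 1.14, neither past the test over all genes. Camera's adjusted p for the list was 1.7e-07, and 0.742 with an estimated correlation, which was also the estimated value of the 5 lists that follow. Of 6 WRKY factors 4 (OsWRKY24, OsWRKY62, OsWRKY71 and OsWRKY76) passed adjusted over the list alone, all with a smaller response in Bala, with a list mean of -2.25 and a camera adjusted p of 0.00455 (0.0659 without Azucena arsenate 3). Of 23 pathogenesis-related proteins and chitinases 4 (PBZ1, Cht6, Cht11 and LOC4351188) passed adjusted over the list alone, with a list mean of -0.95 and a camera adjusted p of 0.00542 (0.120 without Bala control 1, 0.267 without Azucena arsenate 3, 0.280 without Bala arsenate 3). Of 37 jasmonate genes 5 (CM-LOX1, CM-LOX2, OsJAMyb, OsJAZ1 and OsJAZ11) passed adjusted over the list alone, with a list mean of -0.74 and a camera adjusted p of 0.00196 (0.137 without Azucena arsenate 3). Of 69 potassium and metal transporters 9 passed adjusted over the list alone, all with a positive difference, with a list mean of 0.34 and a camera adjusted p of 0.00289 (0.0613 without Azucena arsenate 1). OsCOPT1, at -4.61 ± 0.36 in Azucena and -1.32 ± 0.36 in Bala, had a difference of 3.29 ± 0.51 (limma adjusted p = 0.0627). The 7 metallothioneins had a mean difference of 0.55, 0 passed adjusted over the list alone by limma (1 at an unadjusted p under 0.05), and camera's adjusted p was 0.0158 (0.0588 without Azucena control 1, 0.157 without Azucena arsenate 1, 0.149 without Bala control 3).

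**Figure D3:**
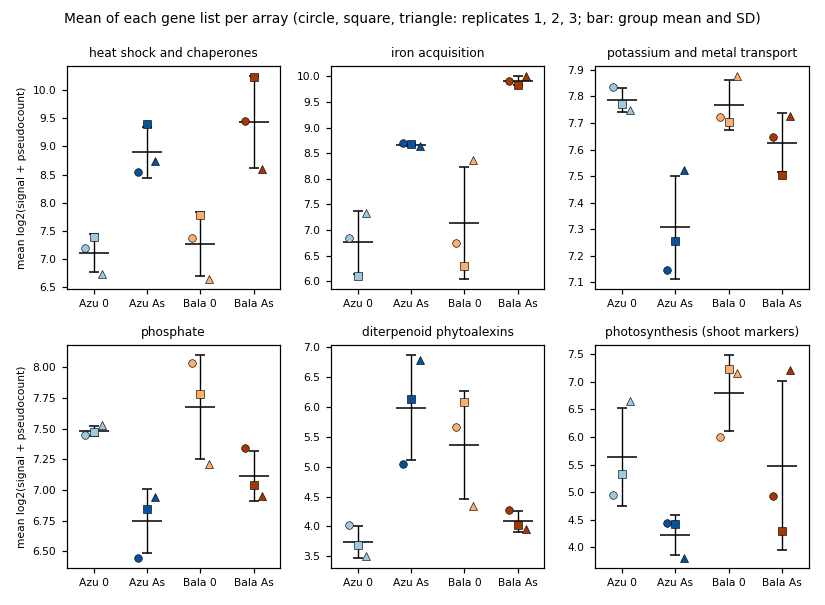
Mean log2(signal + 2.1) of 6 gene lists on each array; Azu and Bala mark the variety, 0 the control and As arsenate, and the bar gives the group mean and SD (n = 3). The phytoalexin list was higher with arsenate in Azucena and lower in Bala, and the shoot markers were lower with arsenate on average in both, with Bala arsenate 3 at 7.20.

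Without arsenate, the roots of both varieties differed in many probe sets, and the largest differences were in genes without a name other than a locus. LOGL3, of the family that activates cytokinins, was at 9.57 ± 7.94 in Azucena and 1093 ± 601 in Bala (log2 difference, Bala minus Azucena, 6.80 ± 0.64). PBZ1, a pathogenesis-related protein, was higher in Bala by 6.26 ± 0.99 and passed in 2 of the 3 fits that left out an experiment (adjusted p 0.0683 without experiment 2). CYP99A2 was higher in Bala by 5.10 ± 0.57 and OsKO4, a P450 of the gibberellin list, by 4.63 ± 0.59. CYP76M7 (-3.72 ± 0.47), OsHsp18.0 (-4.32 ± 0.38), OsAMT3;3 (-2.94 ± 0.39), GST1 (-3.03 ± 0.36) and the disease resistance gene PIK6-NP (-2.21 ± 0.25) were lower in Bala. The comparison asks how the varieties differ before treatment. Limma called 3914 probe sets (1591 higher in Bala, 2323 lower), or 1903 genes (802 higher, 1101 lower), with 615 probe sets at least 4-fold higher and 1084 at least 4-fold lower. In genes with a pair of probe sets, the second bore out 35.6% of the 4-fold higher and 47.4% of the 4-fold lower calls. Probe mismatches to Bala transcripts could not be told apart from lower RNA levels, here or in the comparison with arsenate. The GAPDH 3' to 5' ratio differed as well, at 7.58 to 8.60 in Azucena controls and 1.43 to 2.17 in Bala controls, while those of actin (2.24 to 6.87 and 2.54 to 3.66) and cyclophilin (2.08 to 2.54 and 1.88 to 2.44) overlapped. Of the 194 named genes 61 passed, and 18 of these were lost without a single array, 30 without a whole experiment and 18 in another setting. Largest among genes without another name were LOC4350667 (7.28 ± 0.42) and LOC4346960 (7.03 ± 0.37), higher in Bala, and LOC4328727 (-9.01 ± 0.65), LOC4350213 (-8.27 ± 0.48) and LOC4344270 (-8.16 ± 0.37), lower. In 1 of the varieties CYP99A2, OsKO4, CYP76M7, OsAMT3;3, LOC4350667, LOC4346960, LOC4350213 and LOC4344270 read below the filter value.

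Some defence genes read higher in Bala controls, and no defence list passed camera's test. Of 6 WRKY factors 4 were higher, OsWRKY71 (2.44 ± 0.48), OsWRKY24, OsWRKY62 and OsWRKY76, with a list mean of 1.93 and an adjusted p of 0.0670. The call for OsWRKY24 had an adjusted p of 0.0560 without Bala control 1 and 0.0664 without the replicate block. Of 10 phytoalexin genes 3 (CYP99A2, OsCPS2 and OsDTS2) were higher and 1 (CYP76M7) was lower (mean 1.62, adjusted p 0.0670), of 37 jasmonate genes 4 (CM-LOX1, CM-LOX2, OsJAMyb and OsJAZ11) and 1 (OsJAZ7) (adjusted p 0.0853), and of 23 pathogenesis-related proteins 6 and 2 (Chib3H-h and OsGER3) (adjusted p 0.106). Without Azucena control 2, the adjusted p was 0.177 for CM-LOX2 and 0.0962 for OsJAMyb. Members that passed adjusted over the list alone were 4, 8, 5 and 10. With an estimated correlation the adjusted p of these 4 lists was 0.953. The shoot markers had a mean difference of 1.16 (adjusted p 0.0670, or 0.953 with an estimated correlation). Camera called 0 of 38 lists, with 7 at an unadjusted p under 0.05 (0 with an estimated correlation). Of 1229 genes on chromosome 6, 60 were higher and 73 lower in Bala controls (adjusted p 0.953), and with arsenate 143 rose and 115 fell in Azucena (0.971) and 82 rose and 72 fell in Bala (0.891). The counts adjusted over the list alone were 118, 267 and 155. With an estimated correlation these adjusted p were 0.969, 0.992 and 0.924. The count of 3914 was 2557 without Azucena control 2, and centring arrays on their median moved the median difference from 0.01 to 0.16 and the higher share of the calls from 40.7 to 51.7%.

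With arsenate, 3779 probe sets differed between Bala and Azucena by limma (1578 higher in Bala, 2201 lower), 584 at least 4-fold higher and 1053 at least 4-fold lower. Centring arrays on their median moved the higher share of the calls from 41.8 to 33.7%. Many were those that differed without arsenate: 798 were higher in Bala in both comparisons, against 88.2 for independent lists, and 1536 were lower in both, against 179.6. Here too the shared spread of 1 fit can raise the overlap. In genes with a pair of probe sets, the second bore out 48.7% of the 4-fold higher and 43% of the 4-fold lower calls. LOC4350667 (6.55 ± 0.42) and LOGL3 (3.14 ± 0.64) stayed higher in Bala and LOC4328727 (-9.85 ± 0.65) lower. LOGL3 had an adjusted p of 0.0506 with a pseudocount at the 5th percentile. OsCOPT1 (3.80 ± 0.36), OsIRT2 (4.04 ± 0.49) and OsNramp5 (2.38 ± 0.21) were higher in Bala and OsSWEET12 (-6.18 ± 0.37) and SDH7 (-3.04 ± 0.18), a subunit of succinate dehydrogenase, were lower. LOC4350667, LOC4328727 and OsSWEET12 read below the filter value in the lower variety. The count was 2410 without Bala arsenate 1.

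Of 24 cytochromes P450, 7 rose and 4 fell (AOS4, AOS (LOC4334233), CYP714C2, CYP76M7) in Azucena and 1 rose (CYP71P1) and 7 fell in Bala, and adjusted over the list alone the counts were 12 and 17. By camera the adjusted p was 0.952 and 0.191, or 0.983 and 0.827 with an estimated correlation. Of 37 jasmonate genes, 5 rose (OsOPR1, OsOPR4, OsOPR6, OsGATA17, CM-LOX2) and 5 fell (OsCOI1b, OsCOI1a, AOS4, LOX3, AOS (LOC4334233)) in Azucena, and adjusted over the list alone the count was 11. The adjusted p of camera was 0.970, or 0.992 with an estimated correlation. Of 26 abscisic acid and LEA genes, 6 rose and 4 fell (OsDhn1, OsSAPK3, OsSAPK4, OsABA8ox1) in Bala, and adjusted over the list alone the count was 12. As a list they had a camera adjusted p of 0.809, or 0.914 with an estimated correlation. Of 6 WRKY factors, 0 passed by limma (1 at an unadjusted p under 0.05) in Bala, and adjusted over the list alone the count was 0. For this list the camera adjusted p was 0.601, or 0.914 with an estimated correlation. Of 23 pathogenesis-related proteins and chitinases, 4 rose (OsGER6, OsChia2a, Chib3H-h, Cht11) and 2 fell (Cht10, OsGER7) in Bala, and adjusted over the list alone the count was 10. Camera gave an adjusted p of 0.658, or 0.924 with an estimated correlation. Of 7 NAC factors, 3 rose (OsNAC3, NAC45, OsNAC4) and 1 fell (OsNAC2) in Azucena and 1 rose (NAC45) and 1 fell (OsNAC7) in Bala, and adjusted over the list alone the counts were 4 and 2. By camera the adjusted p was 0.540 and 0.873, or 0.851 and 0.924 with an estimated correlation. Of 11 MYB factors, 1 rose (OsMPH1) and 2 fell (MYBAS1, myb17) in Azucena and 2 fell (MYBAS1, OsJAMyb) in Bala, and adjusted over the list alone the counts were 3 and 3. The adjusted p of camera was 0.425 and 0.313, or 0.757 and 0.827 with an estimated correlation. Of 13 ABC transporters, 3 rose (OsABCG36, OsABCG44, OsABCG50) and 1 fell (OsABCI12) in Azucena and 1 fell (STAR2) in Bala, and adjusted over the list alone the counts were 6 and 2. As a list they had a camera adjusted p of 0.989 and 0.450, or 0.993 and 0.902 with an estimated correlation. Of 11 ethylene genes, 2 rose (OsEIL1 (LOC4332697), ACO1) and 3 fell (OsETR2, OsEIN2, OsETR3) in Azucena and 1 rose (OsEIL1 (LOC4332697)) and 2 fell (OsETR2, OsETR3) in Bala, and adjusted over the list alone the counts were 7 and 4. For this list the camera adjusted p was 0.287 and 0.218, or 0.741 and 0.827 with an estimated correlation. Of 16 gibberellin genes, 4 rose (CIGR1, OsKO4, OsKO5, OsCPS) in Azucena and 1 fell (OsKO4) in Bala, and adjusted over the list alone the counts were 5 and 4. Camera gave an adjusted p of 0.483 and 0.891, or 0.741 and 0.924 with an estimated correlation. Calls of named genes in these lists that were lost without a single array, with the highest adjusted p, were in Azucena ACO1 (0.0965 without Azucena control 1), AOS (LOC4334233) (0.168 without Azucena arsenate 2), CIGR1 (0.131 without Azucena control 3), MYBAS1 (0.116 without Azucena control 1), OsABCG44 (0.0535 without Azucena control 2), OsABCG50 (0.117 without Azucena control 2), OsABCI12 (0.0888 without Azucena control 1), OsCPS (0.0696 without Azucena arsenate 2), OsEIL1 (LOC4332697) (0.0510 without Azucena control 1), OsETR3 (0.125 without Azucena control 2), OsKO5 (0.106 without Azucena arsenate 2), OsMPH1 (0.111 without Azucena control 3) and myb17 (0.0801 without Azucena control 1), and in Bala AOS4 (0.128 without Bala control 1), CYP99A2 (0.0917 without Bala arsenate 1), Chib3H-h (0.0554 without Bala arsenate 1), Cht11 (0.129 without Bala arsenate 3), MYBAS1 (0.164 without Bala arsenate 2), OsEIL1 (LOC4332697) (0.0593 without Bala arsenate 3), OsETR2 (0.115 without Bala arsenate 3), OsETR3 (0.0546 without Bala arsenate 1), OsKO4 (0.108 without Bala control 1), OsNAC7 (0.117 without Bala arsenate 1) and STAR2 (0.114 without Bala control 1).

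Of 7 metallothioneins, 1 fell (OsMT-I-1b) in Azucena and 1 fell (OsMT-I-1b) in Bala, and adjusted over the list alone the counts were 3 and 1. By camera the adjusted p was 0.142 and 0.877, or 0.741 and 0.924 with an estimated correlation. Of 22 antioxidant enzymes, 4 rose (sodCp, OsAPx06, OsAPx04, R1C-Prx) in Azucena and 2 rose (GR, R1C-Prx) and 1 fell (OsAPx01) in Bala, and adjusted over the list alone the counts were 10 and 3. The adjusted p of camera was 0.971 and 0.877, or 0.992 and 0.924 with an estimated correlation. Of 3 class III peroxidases (too few to test as a list), 2 fell (peroxidase (LOC4339222), PRX112) in Azucena and 1 fell (PRX112) in Bala, and adjusted over the list alone the counts were 2 and 1. Of 26 expansins and xyloglucan enzymes, 2 rose (OsEXPB8, OsEXLA3) and 2 fell (OsEXPB2, OsEXLA1) in Azucena and 1 rose (OsEXPB8) in Bala, and adjusted over the list alone the counts were 4 and 0. As a list they had a camera adjusted p of 0.378 and 0.274, or 0.816 and 0.860 with an estimated correlation. Of 33 cellulose and arabinogalactan genes, 1 rose (OsCslE1) in Azucena and 1 rose (OsCslE2) in Bala, and adjusted over the list alone the counts were 0 and 0. For this list the camera adjusted p was 0.136 and 0.196, or 0.741 and 0.827 with an estimated correlation. Of 53 cell cycle and replication genes, 4 rose (OsRPA70c, OsORC1 (LOC4334180), OsRPA32-3, CycB1-1) and 1 fell (CYCD5-1) in Azucena and 1 rose (OspolD1) and 3 fell (CYCD5-1, CYCD5-3, CYCD4-2) in Bala, and adjusted over the list alone the counts were 5 and 1. Camera gave an adjusted p of 0.484 and 0.780, or 0.932 and 0.924 with an estimated correlation. Of 26 ribosomal proteins, 1 rose (RPS10-1) and 1 fell (Ip) in Azucena and 1 fell (Ip) in Bala, and adjusted over the list alone the counts were 0 and 1. By camera the adjusted p was 0.235 and 0.218, or 0.851 and 0.914 with an estimated correlation. Of 31 genes matched by symbol to the glycolysis and fermentation list, 3 rose (NSHB2, GPI-A, HXK4 (LOC4326776)) and 1 fell (PDC (LOC4339066)) in Azucena and 2 rose (NSHB2, OsSUS3) in Bala, and adjusted over the list alone the counts were 2 and 2. The adjusted p of camera was 0.729 and 0.794, or 0.932 and 0.924 with an estimated correlation. Of 13 mitochondrial respiration genes, 1 rose (OsAOX1A) and 1 fell (Ip) in Azucena and 1 rose (OsAOX1A) and 2 fell (Ip, SDH7) in Bala, and adjusted over the list alone the counts were 2 and 3. As a list they had a camera adjusted p of 0.221 and 0.169, or 0.741 and 0.827 with an estimated correlation. Of 6 histones, 0 passed by limma (0 at an unadjusted p under 0.05) in Azucena and 0 passed by limma (1 at an unadjusted p under 0.05) in Bala, and adjusted over the list alone the counts were 0 and 0. For this list the camera adjusted p was 0.760 and 0.794, or 0.851 and 0.914 with an estimated correlation. Of 17 ubiquitin and proteasome genes, 0 passed by limma (2 at an unadjusted p under 0.05) in Azucena and 0 passed by limma (3 at an unadjusted p under 0.05) in Bala, and adjusted over the list alone the counts were 0 and 0. Camera gave an adjusted p of 0.484 and 0.298, or 0.851 and 0.902 with an estimated correlation. Of 9 receptor-like kinases, 0 passed by limma (2 at an unadjusted p under 0.05) in Azucena and 0 passed by limma (2 at an unadjusted p under 0.05) in Bala, and adjusted over the list alone the counts were 0 and 0. By camera the adjusted p was 0.484 and 0.924, or 0.741 and 0.924 with an estimated correlation. Of 5 genes matched by symbol to the seed storage list, 1 rose (AMY1.3) and 1 fell (GLUA-2) in Azucena and 1 rose (AMY1.3) in Bala, and adjusted over the list alone the counts were 2 and 1. The adjusted p of camera was 0.484 and 0.891, or 0.756 and 0.924 with an estimated correlation. Calls of named genes in these lists that were lost without a single array, with the highest adjusted p, were in Azucena AMY1.3 (0.0714 without Azucena control 3), CYCD5-1 (0.0697 without Azucena control 2), CycB1-1 (0.0657 without Azucena control 2), Ip (0.111 without Azucena control 2), NSHB2 (0.147 without Azucena control 2), OsAPx04 (0.0897 without Azucena arsenate 2), OsAPx06 (0.0818 without Azucena control 1), OsCslE1 (0.147 without Azucena control 2), OsEXLA1 (0.0688 without Azucena control 1), OsEXPB8 (0.0730 without Azucena control 1), OsORC1 (LOC4334180) (0.0821 without Azucena control 2), PDC (LOC4339066) (0.0923 without Azucena control 2), PRX112 (0.0569 without Azucena control 2), R1C-Prx (0.121 without Azucena control 2) and RPS10-1 (0.0965 without Azucena control 1), and in Bala CYCD5-1 (0.162 without Bala arsenate 2), Ip (0.110 without Bala arsenate 1), OsAOX1A (0.125 without Bala arsenate 3), OsAPx01 (0.103 without Bala arsenate 1), OsCslE2 (0.168 without Bala arsenate 1), OsEXPB8 (0.142 without Bala arsenate 2) and OsMT-I-1b (0.157 without Bala control 1). The single annotated NB-LRR gene had no call in either variety, and no gene of the ferritin, UDP-glycosyltransferase and MATE lists was matched. In Azucena, the median, the mean and camera's direction differed in sign for ethylene genes (-0.34, 0.07, lower), phenylpropanoid genes (-0.22, 0.13, lower), glycolysis genes (-0.07, 0.11, lower), mitochondrial genes (-0.15, 0.03, lower), histones (0.00, -0.02, lower) and seed storage genes (-0.31, 0.28, lower). In Bala they differed for metallothioneins (0.22, -0.09, higher), auxin genes (0.01, -0.02, lower), gibberellin genes (0.13, -0.03, lower), pathogenesis-related proteins (-0.12, 0.05, lower), histones (0.02, -0.06, lower), potassium and metal transporters (0.01, -0.14, lower) and seed storage genes (-0.05, 1.02, higher). They also differed for arsenic handling, abscisic acid, MYB, phenylpropanoid, expansin, cellulose, mitochondrial and chromosome 6 genes in the difference between the varieties, and for sulfate, arsenic handling, heat shock, phenylpropanoid, histone, metal transporter, seed storage and chromosome 6 genes between the controls. None of these lists passed camera's test in the contrast concerned.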

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

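The tests of 1 array, of shoot tissue and of probe mismatches for the phytoalexin genes were chosen only after the result was seen, and that of fungal RNA was not.

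The arsenate response differed between the varieties for 26 probe sets by limma. The 11 genes among them were OsSWEET1b (5.26, Bala minus Azucena), LOC4344909 (4.45), LOC9267438 (2.85), OsSWEET12 (-6.10), CYP99A2 (-5.98), LOC4334549 (-4.97), LOC4343962 (-4.30), LOC4339856 (-3.80), LOC4326969 (-3.56), LOC4326000 (-3.37) and LOC4342259 (-2.74). By camera with the preset correlation 6 lists differed, with means of 0.55 for metallothioneins, 0.34 for potassium and metal transporters, -0.74 for jasmonate genes, -0.95 for pathogenesis-related proteins and chitinases, -2.25 for WRKY factors and -3.53 for phytoalexin genes. With an estimated correlation no list passed (adjusted p 0.742 at the lowest), 1 at an unadjusted p under 0.05.

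The phytoalexin genes were higher with arsenate in Azucena and lower in Bala on average, and the difference was below 0 in each experiment (-2.41, -4.50 and -3.67). A single array does not account for it: the mean difference nearest to 0 was -2.90, without Azucena arsenate 3. For fungal RNA in the Bala control pots, Bala minus Azucena controls was 0.149 over 10 fungal control probe sets (SD of arrays within groups 0.480). These probe sets are for Magnaporthe only, and most of their control signals lay below the filter value. They therefore cannot exclude fungal RNA, which stays open. Probe mismatches to Bala transcripts are argued against for the mean of the phytoalexin genes. In the controls this mean was higher in Bala by at least 0.838 in each experiment. The values do not cover CYP76M7, which read lower in Bala controls. For the difference, shoot tissue in the samples stays open: the shoot markers differed by -0.57 and -2.03 in experiments 1 and 2, with the phytoalexin genes, and by 2.88 in experiment 3, against them, which rests on 1 array per group. In Azucena the phytoalexin genes rose in experiments 1, 2 and 3 (1.03, 2.43 and 3.28) while the shoot markers fell (-0.49, -0.89 and -2.83). These values argue against added shoot tissue as the source of the rise in Azucena. In Bala the phytoalexin genes changed by -1.38, -2.07 and -0.39 and the shoot markers by -1.07, -2.93 and 0.05. Shoot tissue therefore stays open for the fall in Bala. Without arsenate both lists read higher in Bala in each experiment, the shoot markers by 1.06, 1.90 and 0.50. A biological difference between the varieties stays open too, as untested, and the higher level in Bala controls is part of the pattern.

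Control probe sets for the rice blast fungus Magnaporthe, outside the rice measurement, had their highest mean in Bala arsenate 1, 3.68 on the log2 scale over 10 probe sets, where the other arrays went down to 1.90. Among these, AFFX-Mgr-ef1a-3 had a signal of 57.9 in Bala arsenate 1 and 55.2 in Bala arsenate 2, and AFFX-Mgr-actin-3 had 34.0 and 30.1. In Azucena arsenate 1 and 2, AFFX-Mgr-ef1a-3 read 9.6 and 14.5, against 0.6 to 1.4 in Azucena controls. In experiment 3 it read 0.5 in the arsenate arrays of both varieties, and the higher readings of this probe set stood in experiments 1 and 2. The source of this signal was not tested.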

How the results depend on the processing

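The fit without Azucena control 3 and Bala arsenate 3 was chosen only after the data were seen. The number of probe sets past the threshold for the difference between the varieties, 26, was 58 without the replicate block (22 shared), 17 and 138 with pseudocounts at the 5th and 50th percentile (15 and 24 shared), 5 without the filter (OsSWEET1b, LOC4344909, OsSWEET12, LOC4343962 and 1 probe set with no gene), 56 with the filter at the 70th percentile (15 shared), 71 with arrays centred on their median (26 shared), 77 with trend and robust options (19 shared), and 1 (OsSWEET1b) without both number 3 arrays. With quantile normalization it was 31 (24 shared). Without the filter the counts were 3102 for Azucena, 1602 for Bala and 5966 for the average, and with only the groups compared 3656 for Azucena and 1553 for Bala. With the filter at the 70th percentile Bala minus Azucena with arsenate had 2484. Without both number 3 arrays Bala had 1886 and the controls 2604. Lists past camera's threshold were 21 in all with the preset correlation, 0 with an estimated one, 23 without the replicate block and 22 with quantile normalization. Fewer arrays or more probe sets tested account for part of this by construction, and otherwise the cause was not tested.

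With each array or experiment left out, the counts ranged from 858 to 6539 for Azucena, 429 to 3730 for Bala, 3216 to 9407 for the average, 0 to 97 for the difference (0 without each experiment, with 2114, 1461 and 4773 by limma at an unadjusted p under 0.05), 1748 to 4184 for the controls and 1653 to 4138 with arsenate. Values that had not passed changed sign in a few of these fits: OsLPT1 in Bala (between -2.48 without replicate 3 and 0.41) was 0.10 without replicate 1, 0.41 without replicate 2, 0.13 without Bala control 1, 0.05 without Bala control 2 and 0.05 without Bala arsenate 2, OsPHO1;2 in Bala (lowest -0.37, without replicate 3) was 0.29 without replicate 2, 0.15 without Bala control 2 and 0.19 without Bala arsenate 2, and OsPht1;8 in Azucena was -0.19 without Azucena arsenate 3 (highest 0.87, without Azucena arsenate 1). Of 194 results past the threshold, each a named gene in the contrast that named it, 46 were lost without a single array, 102 without an array or experiment and 43 in another setting, and 0 changed sign. Signal over background limits low probe sets, since the filter value of 9.4 lies near the array medians.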

Other observations

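The tests of the larger response in Azucena and the comparison with 32 splits were chosen only after the result was seen, while the other splits of the arrays and the test on genes with a pair of probe sets were not.

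Single cell wall, redox, auxin and cytoskeleton genes also responded to arsenate, though no list of theirs passed camera's test. The laccases LAC19 (6.15 ± 0.48 in Azucena, 4.83 ± 0.48 in Bala) and LAC24 (5.19 ± 0.44 and 4.12 ± 0.44), of a family that polymerises lignin, rose, and the 4-coumarate ligase genes 4CL (-2.58 ± 0.19 and -1.94 ± 0.19) and 4CLL7 (-3.63 ± 0.30 and -3.19 ± 0.30) fell. The glutaredoxin GRXS3 rose by 4.35 ± 0.22 and 2.16 ± 0.22. The auxin repressor IAA6 fell in both (-1.72 ± 0.16 and -1.36 ± 0.16). Some tubulins fell and some kinesins, the motor proteins that move along microtubules, rose, with OsTUB8 at -1.66 ± 0.17 and -1.29 ± 0.17. The alternative oxidase OsAOX1A, a mitochondrial enzyme of stress responses, rose by 3.09 ± 0.46 in Azucena. Of 31 phenylpropanoid and lignin genes, 3 rose (LAC24, LAC19, OsCCR1) and 5 fell (PAL, Cfi, LAC7, 4CLL7, 4CL) in Azucena and 2 rose (LAC24, LAC19) and 4 fell (OsCAD1, Cfi, 4CLL7, 4CL) in Bala, and adjusted over the list alone the counts were 9 and 6. As a list they had a camera adjusted p of 0.142 and 0.245, or 0.816 and 0.914 with an estimated correlation. Of 36 thioredoxins and glutaredoxins, 4 rose (OsNrx1-2, GRXS4, GRXS3, GRXC3) and 1 fell (OsTrx03) in Azucena and 4 rose (GRXS7, GRXS3, GRXC3, OsNrx2) in Bala, and adjusted over the list alone the counts were 4 and 4. For this list the camera adjusted p was 0.484 and 0.891, or 0.851 and 0.924 with an estimated correlation. Of 63 auxin response genes, 4 rose (IAA9, OsETTIN1, IAA26, IAA20 (LOC4340245)) and 9 fell in Azucena and 3 rose (IAA23, IAA26, IAA20 (LOC4327919)) and 5 fell (IAA6, OsGH3-6, ARF10, ILL6, OsYUCCA1) in Bala, and adjusted over the list alone the counts were 13 and 8. Camera gave an adjusted p of 0.142 and 0.658, or 0.741 and 0.914 with an estimated correlation. Of 44 tubulins and kinesins, 7 rose and 5 fell (TubA, OsTUB6, pTUB22, OSTB-16, OsTUB8) in Azucena and 5 rose (K23, KIN14A, KIN14B, KIN14I, KIN12E) and 2 fell (pTUB22, OsTUB8) in Bala, and adjusted over the list alone the counts were 12 and 7. By camera the adjusted p was 0.764 and 0.245, or 0.983 and 0.914 with an estimated correlation. Calls of named genes in these lists that were lost without a single array, with the highest adjusted p, were in Azucena OsNrx1-2 (0.0717 without Azucena control 2) and OsTrx03 (0.0734 without Azucena control 2), and in Bala GRXC3 (0.114 without Bala arsenate 3).

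Of the 9033 probe sets of the averaged effect, 63.0% had the larger absolute change in Azucena, with medians of 0.98 in Azucena and 0.81 in Bala in the direction of the call. Probe mismatches to Bala transcripts as the whole cause are argued against by the share among 4781 probe sets that read no lower in Bala, 64.1%. A single array is argued against too, since the lowest share with 1 array left out was 56.6%, without Bala control 2. The experiments were not alike: the share was 62.6% in experiment 1, 64.9% in experiment 2 and 47.6% in experiment 3, so that a candidate explanation is that experiments 1 and 2 carry the pattern. A difference between the varieties stays open, as untested.

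Between the controls 615 probe sets were at least 4-fold higher in Bala and 1084 at least 4-fold lower. The imbalance was smaller in other scalings, with 665 and 1036 after quantile normalization, and 738 and 986 with arrays centred on their median. If probe mismatches to Bala transcripts were the source, a second probe set of the same gene would bear out lower calls less often. It did so for 45 of 95 lower calls (47.4%) and 16 of 45 higher calls (35.6%), a difference of 11.8 percentage points (Fisher's exact test, two-sided, p = 0.206). For 4-fold calls with arsenate the share was 68.6% of higher and 61.7% of lower calls in Azucena, and 65.1% and 61.8% in Bala. Between the varieties with arsenate it was 48.7% of higher and 43% of lower calls. Why calls between the varieties were borne out less often was not tested. With so few pairs, mismatches and a difference between the varieties cannot be told apart.

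For the averaged effect 1 of 100 splits of the arrays within varieties, the real one, gave as many probe sets (9033, highest other 39). Of the 32 splits that, like the real one, part control from arsenate labels within every experiment, 1 did, with 165 as the highest other. Both sets argue against chance, but the 32 splits were chosen after the result was seen and allow no share below 1 in 32. Neither set tells arsenate apart from the 3' to 5' ratios, of which those of GAPDH and actin were higher with it in each experiment. Nor does either set tell it apart from the shoot markers, though these moved with it only in part. In experiment 3 of Bala they read 7.15 in the control and 7.20 with arsenate. For the difference between the varieties 3 of 100 splits gave at least 26 (highest other 9033), but so did 4 of those 32, and chance is not excluded. The others gave 39, 165 and 9033: they left Azucena as it was and exchanged the labels of Bala in 1, 2 and all 3 experiments. The last returns the averaged effect, a structure of the samples, and those with 39 and 165 carry part of it into the difference. These splits therefore cannot judge chance for the difference. For Azucena, Bala and both comparisons between the varieties, 1 of 10 splits, the real one, gave as many (5989, 3379, 3914 and 3779, highest other 0 in each), and 10 splits are too few for a share under 0.05.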
